A study of Mus musculus with 8 samples.

How the data were processed

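Messenger RNA was measured in mouse kidneys on 8 single-colour Agilent arrays, 2 in each of 4 groups: wild-type (WT) and Keap1 knockdown (KD) kidneys, either without injury (normal) or at day 1 after ischemia-reperfusion injury (IRI). Per the labels, each array received Cy3-labelled material made from 300 ng of total RNA. Per the file headers, the spot values are fluorescence intensity on a linear scale, background-subtracted and detrended by Agilent Feature Extraction 10.7.3.1. The deposited value table of the series holds log2 values. Its columns tracked the log2 intensity scaled to the 75th percentile of each array and centred on each probe's median over the 8 arrays, with r between 0.999982 and 0.999992. The medians of its columns were 0.158 and 0.124 in WT normal, 0.0951 and 0.0560 in KD normal, -0.0744 and -0.0814 in WT IRI, and -0.136 and -0.117 in KD IRI, so the columns were not centred on a common value. How the authors scaled it is not stated in the labels and was inferred from the values.

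The fitted values were the log2 of the processed intensity minus the log2 of each array's 75th percentile. Control spots and spots marked as outliers by Feature Extraction were left out, and the spots of a probe were averaged. A probe was kept when it was well above background on both arrays of at least 1 group, which kept 27408 of 41174 probes. Gene symbols came from a table of RefSeq accessions for a later mouse assembly than that of the array design, used for names and neighbours but not for positions. It named 26690 probes with 18217 distinct symbols. Probes without a symbol kept the identifier in the file. For each name the probe with the brightest mean over the 8 arrays was used, which gave 20580 genes to test, 14104 of them with a symbol; 5293 had more than 1 kept probe. A "gene" without a symbol is an array identifier, and several can belong to 1 gene.

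Group means were fitted with limma 3.58.1 in R 4.3.3 (data handling with the data.table package, version 1.17.8), using all 8 arrays and empirical Bayes moderation with an intensity trend. The fit had 4 residual degrees of freedom and a median of 2.925 prior degrees of freedom. Each of 5 contrasts was tested two-sided, with Benjamini-Hochberg adjustment over the 20580 genes and a threshold of 0.05. The contrasts were WT IRI against WT normal, KD normal against WT normal, KD IRI against WT IRI, KD IRI against KD normal, and the interaction, which is the injury response of KD minus that of WT. Standard errors (SE) are limma's moderated ones, spreads of group values are standard deviations (SD), and n is 2 arrays per group throughout. The labels do not say that each array is a separate animal, so the p-values measure the spread between these samples. A gene below background on both arrays of a group is given as a lower bound on its fold, with its signal there set to at least the lowest signal called well above background on that array. The number of arrays limits the precision.

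The choices in this paragraph were fixed before the data were examined. The 25 gene lists cover NRF2 targets (glutathione, redox and detoxification, NADPH supply), tubule injury, immediate-early genes, inflammation, neutrophils, monocytes and macrophages, and lymphocytes. They also cover proximal tubule, loop and distal tubule, collecting duct, podocytes, endothelium, and matrix and stroma. The rest are fatty acid oxidation, gluconeogenesis and fructose use, the TCA cycle and oxidative phosphorylation, cell cycle, hypoxia and glycolysis, heat shock with the unfolded protein response and ATF4 targets, cell death, blood, fat and adrenal, and housekeeping. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists within a contrast, and again with an estimated correlation and with limma's fry. Genes are named by a rule. These are always Keap1, Nfe2l2, Nqo1, Gclc, Gclm, Hmox1, Txnrd1, Havcr1, Lcn2 and Slc34a1. Added are the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between the groups (this last condition not applied to the interaction), leaving out names that are accessions or clone names. From each list come up to 2 members with the largest rise, up to 2 with the largest fall and the largest change among those not past the threshold. Not every gene named by the rule is reported in the text.

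The following were also run, as fixed in advance: quantile normalization, normexp background correction with an offset of 50, the deposited log2 table, and 2 other filters on dim probes. So were no intensity trend, array weights, only the arrays compared, a block for the slide, the mean of all probes of a gene, single probes, a fold minimum of 2, and leaving out each array in turn. The files lack the mean spot intensity planned for normexp, and the median was used. An additional normexp fit without non-uniform spots was chosen after the planned one had been seen to change results. Each of the 2 slides held 1 array of every group, scanned on the same day, and the slide number equals the replicate number, so the slide block and the replicate block are the same fit. A scan-date block was not possible with 1 scan day. Each group had the same position on both slides, so position and group cannot be told apart.

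The fit was tested on simulated data with 20580 genes and the spread of each gene on these arrays. Noise was drawn independently for each gene, and 66 or 67 genes were changed at each size of change. Of the genes given a log2 change of 1, between 47.8% and 59.7% were recovered, depending on the comparison. At a log2 change of 0.5 the share was 13.4% to 17.9%, and at 2 it was 78.8% to 84.8%. False calls made up 4.46% to 7.62% of the simulated calls. In the real comparisons many more genes were called and genes are correlated, so these shares need not hold there. The interaction was not simulated.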

Results

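Gene expression was measured in kidneys of male mice aged 16 weeks on 8 single-colour arrays, 2 in each of 4 groups. Wild-type (WT) kidneys and kidneys with a knockdown (KD) of Keap1 were taken without injury (normal) or at day 1 after ischemia-reperfusion injury (IRI), in which the blood vessels of the left kidney had been clamped for 45 min. Keap1 encodes the adaptor protein that marks NRF2 for degradation. NRF2, encoded by Nfe2l2, is a transcription factor that drives genes of glutathione synthesis, detoxification and NADPH supply. Each array held 45018 spots, 43379 of them not controls, and none of the latter was saturated. The share of spots well above background was 62.1% on both WT normal arrays, 63.2% and 64.5% in KD normal, 67.3% and 67.8% in WT IRI, and 66.1% and 65.7% in KD IRI. Across genes, which are not independent replicates, the 2 arrays of a group correlated with r = 0.994 in WT normal, 0.9899 in KD normal, 0.989 in WT IRI and 0.994 in KD IRI. The first principal component held 74.9% of the variance and placed the normal kidneys between -80.7 and -73.3 and the injured kidneys between 50.9 and 101.6. The second held 10.4% and placed KD normal at 30.3 and 49.0 and WT normal at -38.7 and -39.0. In what follows, changes are log2 differences with the SE of limma and n = 2 arrays per group, and p-values are adjusted values from limma.

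Keap1 was lower in the knockdown kidneys, with and without injury. Its level, as log2 signal over the array's 75th percentile, was 2.74 ± 0.062 (SD, n = 2) in WT normal, 1.48 ± 0.063 in KD normal, 2.63 ± 0.11 in WT IRI and 1.24 ± 0.20 in KD IRI. It fell by 1.26 ± 0.11 (SE) in KD normal against WT normal (adjusted p = 0.00391) and by 1.39 ± 0.11 in KD IRI against WT IRI (adjusted p = 0.00498). Within slides these differences were -1.26 on both slides without injury, and -1.33 and -1.46 with injury. When only the 4 arrays compared were fitted, the adjusted p of the injured comparison was 0.0503. Injury did not move Keap1 past the threshold in WT (-0.11, adjusted p = 0.466) or in KD (-0.25, adjusted p = 0.103). Nfe2l2 passed in none of the 5 comparisons, with changes of -0.18 without injury (adjusted p = 0.333) and -0.16 with injury (adjusted p = 0.419) between the genotypes.

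**Figure D1:**
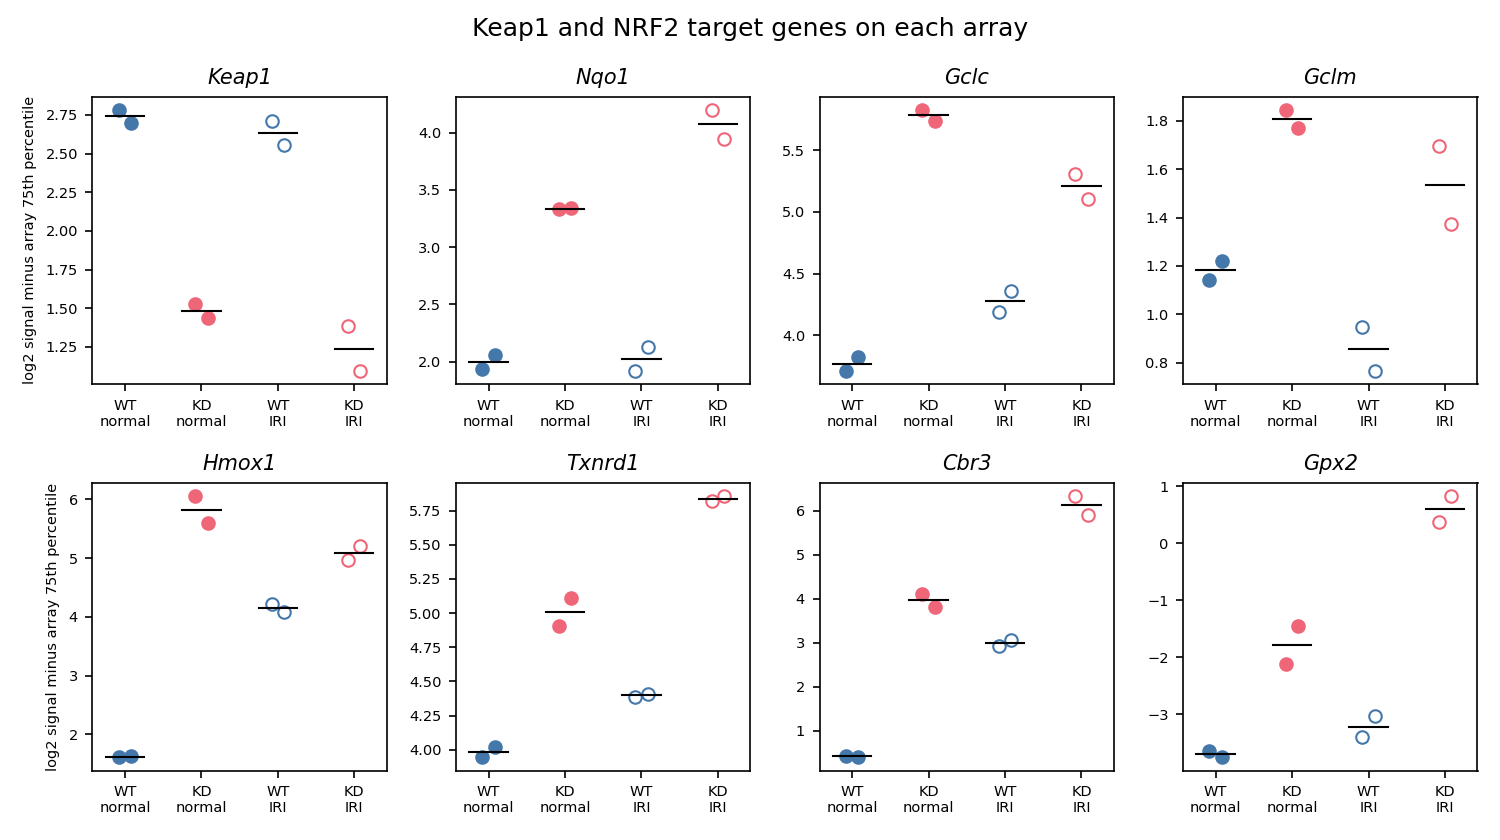
Log2 signal minus the array's 75th percentile of Keap1 and 7 genes of the NRF2 lists on each array, by group (points, arrays; lines, means of 2 arrays; blue, WT; red, KD; filled, normal; open, IRI). Keap1 lies between 2.63 and 2.74 in the WT group means and between 1.24 and 1.48 in the KD group means.

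The comparison of WT IRI with WT normal asks how a wild-type kidney responds to injury. Genes of injured tubules rose: Havcr1, which encodes the injury marker KIM-1, was 503-fold higher (log2 8.97 ± 0.37, adjusted p = 3.21e-05), Krt20, a keratin, 505-fold, and Lcn2, which encodes the iron-binding protein NGAL, 146-fold. Of the 24 tubule injury genes 23 rose, none fell and 1 did not pass, with a median of 2.97. Sprr2f, a gene of epithelial barriers, was at least 204-fold higher, and the member that did not pass was Igfbp1 at -0.66 (adjusted p = 0.484). Transporters and enzymes of the proximal tubule fell: of 27 measured genes 24 fell, 1 rose and 2 did not pass, with a median of -1.45. Slc22a7, an organic anion transporter, fell by 6.81 ± 0.29 on the log2 scale, the amino acid transporter Slc7a13 by 4.92 and the phosphate transporter Slc34a1 by 1.97, whereas the sulfate transporter Slc13a1 rose by 0.88. Camera gave an adjusted p of 2.51e-13 for tubule injury (adjusted p = 0.27 with an estimated correlation) and 7.12e-08 for proximal tubule (adjusted p = 0.312 with an estimated correlation). Adjusted over the list alone, 23 tubule injury genes rose and 25 proximal tubule genes fell.

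Inflammatory genes and markers of neutrophils and macrophages were also higher after injury in WT, whereas no lymphocyte marker rose. Of 21 inflammation genes 16 rose, none fell and 5 did not pass (19 rose adjusted over the list alone). The chemokine Ccl7 was at least 14.2-fold higher, the decoy receptor Il1r2 at least 25-fold, and Cxcl10 did not pass (1.01, adjusted p = 0.0629). The list's median was 1.91, or 1.06 with genes below background at their bound. Of 11 neutrophil markers 9 rose and 2 did not pass, with a median of 5.62, or 3.73 with bounds: S100a9 was 321-fold higher and S100a8 at least 195-fold. Among 17 monocyte and macrophage markers 15 rose, 1 fell and 1 did not pass, with a median of 1.74. Chil3 was 199-fold higher, whereas Csf1r, the receptor for the growth factor CSF1, fell by 0.95 on the log2 scale. Of 11 lymphocyte markers 4 fell, among them Cd3d (-1.89) and Nkg7 (-1.66), none rose and 7 did not pass. By camera, the adjusted p was 1.65e-08 for inflammation (adjusted p = 0.116 with an estimated correlation) and 6.16e-05 for neutrophils (adjusted p = 0.322 with an estimated correlation). It was 9.09e-07 for monocytes and macrophages (adjusted p = 0.286 with an estimated correlation) and 0.0213 for lymphocytes (adjusted p = 0.351 with an estimated correlation). The lymphocyte median of -1.05 became 0.53 under the planned normexp correction, and without WT IRI 2 it was -0.55 (camera adjusted p = 0.0822). The neutrophil median was 2.77 under the planned normexp correction and 2.59 under the added one, and that of inflammation 1.58 and 0.92.

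Genes of energy metabolism fell in injured WT kidney while genes of cell division rose. Of 24 fatty acid oxidation genes 21 fell, none rose and 3 did not pass, with a median of -1.003. Acadm, a dehydrogenase of medium-chain fatty acids, fell by 2.08 ± 0.12 on the log2 scale and Acaa1b by 1.66. All 9 genes of gluconeogenesis and fructose use fell (median -1.74), such as the fructose transporter Slc2a5 (-2.25) and the kinase Khk (-2.10), and so did all 21 of the TCA cycle and oxidative phosphorylation (median -0.84), such as Idh2 (-1.62). Of 20 cell-cycle genes 19 rose, with a median of 2.15. Mcm5, part of the DNA replication helicase, rose by 3.68 and the mitotic kinase Aurkb was at least 8.45-fold higher. Bub1 was the member called lower (-1.41), and its other probe was called in the opposite direction. With camera the adjusted p came to 1.19e-07 for fatty acid oxidation (adjusted p = 0.27 with an estimated correlation) and 8.00e-05 for gluconeogenesis (adjusted p = 0.307 with an estimated correlation). It was 8.41e-09 for the TCA cycle (adjusted p = 0.286 with an estimated correlation) and 1.65e-08 for cell cycle (adjusted p = 0.308 with an estimated correlation). Counts adjusted over the list alone were the same for these 4 lists. Quantile normalization gave medians of -0.61 for fatty acid oxidation and -0.47 for the TCA cycle.

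Other groups in the same comparison moved as follows. All 12 loop and distal tubule genes fell (median -1.32; camera adjusted p = 1.24e-06; adjusted p = 0.116 with an estimated correlation): Pvalb, a calcium-binding protein of the distal tubule, was at least 60.8-fold lower and the growth factor gene Egf was 50-fold lower. Of 13 collecting duct genes 11 fell, among them Slc4a1 (-2.86), which is also in the blood list, and Aqp4 (-1.71), and 2 did not pass (median -0.80, camera adjusted p = 8.00e-05, adjusted p = 0.27 with an estimated correlation). Matrix and stroma genes rose in 15 of 17, as for Tnc (3.998), with 2 not passing (median 2.03; camera adjusted p = 8.41e-09; adjusted p = 0.307 with an estimated correlation). The immediate-early list rose in 8 of 11, including Egr2 (4.29) and Fos (at least 3.81-fold), with 3 not passing (median 1.501; camera adjusted p = 5.35e-05; adjusted p = 0.307 with an estimated correlation). Cell death genes rose in 8 of 16, among them Ripk3 (2.91) and Mlkl (2.69) of necroptosis, with 8 not passing (median 0.61; camera adjusted p = 0.000189; adjusted p = 0.307 with an estimated correlation). Of 18 heat-shock and stress-response genes 6 rose, such as Hspb1 (3.64), 1 fell, Herpud1 (-1.17), and 11 did not pass (median 0.24; camera adjusted p = 0.0231; adjusted p = 0.349 with an estimated correlation).

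Among NRF2 targets in injured WT kidney, 11 of 22 redox and detoxification genes rose, 3 fell and 8 did not pass (median 0.37, 0.66 under quantile normalization and 0.19 under the planned normexp correction; camera adjusted p = 0.00268; adjusted p = 0.27 with an estimated correlation). Akr1b8, an aldo-keto reductase, rose by 3.40, Cbr3, a carbonyl reductase, by 2.59 and Hmox1, the heme oxygenase, by 2.53. Nqo1, a quinone reductase, was at 0.02 (adjusted p = 0.883). The NADPH list had 6 rises, 2 falls and 1 not passing (median 0.52, or 0.90 under quantile normalization; camera adjusted p = 0.0634), and the glutathione list 8 rises, 8 falls and 4 not passing (camera adjusted p = 0.859). In the glutathione list the median was -0.07 (0.042 under quantile normalization), the mean 0.14 and the test pointed up. Its cystine transporter Slc7a11 was at least 2.95-fold higher and its member Gstm2 fell by 1.32. The endothelial list had 3 rises, 1 fall and 9 not passing (camera adjusted p = 0.0634). For podocytes these counts were 1, 1 and 8 (camera adjusted p = 0.418; median 0.16, mean -0.31), and for hypoxia and glycolysis 4, 6 and 10 (camera adjusted p = 0.663; median -0.14, or 0.17 under quantile normalization, mean 0.025). Fat and adrenal markers had 1 rise, 1 fall and 5 not passing (camera adjusted p = 0.76; median 0.15, mean -0.20), and housekeeping genes 1, 3 and 6 (camera adjusted p = 0.584). All 3 blood markers measured fell, Slc4a1 among them (median -2.24, camera adjusted p = 0.068).

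In total 9397 of 20580 genes changed in WT IRI against WT normal, 4374 higher and 5023 lower, and 3448 of them by at least 2-fold. The balance of rises and falls depended on the scaling. Quantile normalization gave 5066 higher and 4371 lower, whereas both normexp fits and the deposited log2 table gave more falls than rises. The change correlated between slides with r = 0.867 across genes, and a slide block gave 10106. Within slides the median was 2.54 and 3.08 for tubule injury, 2.50 and 1.91 for inflammation, -1.21 and -1.79 for proximal tubule, -1.12 and -0.79 for fatty acid oxidation and 2.69 and 1.55 for cell cycle. The count was 5891 without WT normal 1 and 6109 without WT normal 2, 5202 with the planned normexp correction and 15081 without the filter on dim probes. Of 80 named genes past the threshold 72 kept their call in each of the 8 fits that left out 1 array. The others, including Nkg7, reached an adjusted p between 0.0527 and 0.162 in 1 or more of them.

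The comparison of KD normal with WT normal asks what lower Keap1 does in the uninjured kidney. NRF2 targets were higher: Hmox1 rose 18.4-fold (log2 4.20 ± 0.16, adjusted p = 0.000641), Cbr3 11.7-fold (3.55 ± 0.16). Gclc, which encodes the catalytic subunit of the enzyme that starts glutathione synthesis, rose 4.03-fold (2.01 ± 0.099), Nqo1 2.53-fold (1.34 ± 0.11) and Txnrd1, a thioredoxin reductase, 2.03-fold (1.02 ± 0.084). Of 20 glutathione genes 15 rose, none fell and 5 did not pass (15 adjusted over the list alone), with a median of 0.92, or 0.74 with genes below background at their bound. Gpx2, a glutathione peroxidase, rose by 1.93 and Gclm, the regulatory partner of Gclc, by 0.63, while Slc7a11 did not pass (1.01, adjusted p = 0.302). Of 22 redox and detoxification genes 14 rose and 8 did not pass (15 adjusted over the list alone), with a median of 0.88. Osgin1 did not pass (0.58, adjusted p = 0.135). Of 9 NADPH genes 5 rose and 4 did not pass (7 adjusted over the list alone), with a median of 0.57, among them Idh1 (0.89). In camera's test the adjusted p was 2.00e-11 for glutathione (adjusted p = 0.233 with an estimated correlation), 9.18e-13 for redox and detoxification (adjusted p = 0.0776 with an estimated correlation) and 7.02e-05 for NADPH supply (adjusted p = 0.233 with an estimated correlation).

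Part of the stress-response genes were higher in the uninjured KD kidney too. Of 11 immediate-early genes 7 rose and 4 did not pass (9 adjusted over the list alone), with a median of 0.97. The transcription factor Egr2 rose 8.81-fold and Fos at least 1.51-fold. Of 18 heat-shock and stress-response genes 9 rose and 9 did not pass (11 adjusted over the list alone), with a median of 0.80. The chaperone genes Hspb1 and Hsph1 rose by 2.20 and 1.60. The tubule injury list had 8 rises and 16 not passing (11 rises and 1 fall adjusted over the list alone; median 0.62), including the cell-cycle inhibitor Cdkn1a (2.92) and Sprr2f (at least 3.47-fold). Havcr1 (0.99, adjusted p = 0.113) and Lcn2 (0.58, adjusted p = 0.493) did not pass. Camera's adjusted p was 4.43e-06 for immediate-early genes (adjusted p = 0.373 with an estimated correlation), 5.70e-07 for the heat-shock list (adjusted p = 0.233 with an estimated correlation) and 5.45e-05 for tubule injury (adjusted p = 0.509 with an estimated correlation). With fry the tubule injury list had an adjusted p of 0.0647.

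In the uninjured KD kidney the cell-cycle, collecting duct, loop and distal tubule, fatty acid oxidation and lymphocyte lists passed camera downward at the preset correlation, although most of their genes did not pass singly. Of 20 cell-cycle genes 4 fell and 16 did not pass (11 fell adjusted over the list alone), with a median of -0.70, or -0.089 under the planned normexp correction. Ccnb1, a mitotic cyclin, was at least 1.35-fold lower. Of 13 collecting duct genes 6 fell, such as Slc4a1 (-1.44), also in the blood list, and Hsd11b2 (-1.06), and 7 did not pass. Of 12 loop and distal tubule genes 3 fell, such as the sodium chloride transporter Slc12a3 (-0.80), and 9 did not pass. Of 24 fatty acid oxidation genes 4 fell and 20 did not pass. Of 11 lymphocyte markers 3 fell, such as Cd79b (-1.69), and 8 did not pass. Their median of -0.78 became 0.29 under the planned normexp correction. Camera gave an adjusted p of 0.000257 for cell cycle (adjusted p = 0.565 with an estimated correlation; fry 0.154) and 0.00919 for collecting duct (adjusted p = 0.373 with an estimated correlation). It was 0.0174 for loop and distal tubule (adjusted p = 0.233 with an estimated correlation), 0.0459 for fatty acid oxidation (adjusted p = 0.565 with an estimated correlation; fry 0.081) and 0.00919 for lymphocytes (adjusted p = 0.499 with an estimated correlation; fry 0.0614). Without KD normal 2 the lymphocyte median was -0.27 (camera adjusted p = 0.0673); it was -0.52 without WT normal 1 and -1.37 without KD normal 1. Without KD normal 1 collecting duct had a camera adjusted p of 0.0522. Fatty acid oxidation had 0.0738 without WT normal 1, 0.0533 without WT normal 2, 0.138 without KD normal 2 and 0.0543 without KD IRI 1 or KD IRI 2. Proximal tubule genes had a median of 0.09, with 1 rise, no fall and 26 not passing (camera adjusted p = 0.389). The lists of neutrophil (median 0.87, or 0.29 with bounds; camera adjusted p = 0.0646), macrophage (0.08; camera adjusted p = 0.897, the test pointing down) and inflammation genes (0.16; camera adjusted p = 0.133) did not pass. Under the planned normexp correction the medians were -0.068 for proximal tubule, 0.34 for macrophages and 0.92 for inflammation. Among the largest changes outside the lists were those of Angptl7, an angiopoietin-like protein (5.41), Alkal2, a ligand of the receptor ALK (at least 12.6-fold higher), and Grem1, an antagonist of bone morphogenetic proteins (at least 7.05-fold higher). Others were Ugt2b35, a glucuronosyltransferase (at least 5.43-fold higher), Clic6 (at least 4.52-fold lower) and Rec8, a cohesin of meiosis (-2.55).

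Between the uninjured genotypes 3147 genes changed, 1305 higher and 1842 lower, 897 of them by at least 2-fold. The change correlated between slides with r = 0.6 across genes, and the count was 3727 with a slide block. Medians within slides were 0.82 and 0.84 for glutathione, 0.76 and 0.95 for redox and detoxification, 0.47 and 0.78 for NADPH supply, 0.90 and 1.18 for immediate-early genes, 0.95 and 0.58 for heat shock and -0.64 and -0.98 for cell cycle. The count was 247 without WT normal 1, 122 without WT normal 2, 1515 without KD normal 2, 1948 without KD IRI 1 and 1946 without KD IRI 2, 1326 with the planned normexp correction and 1981 without the filter on dim probes. Of 61 named genes past the threshold, 15 kept their call in each of the 8 fits that left out 1 array. They include Hmox1, Cbr3, Gclc, Nqo1, Txnrd1, Egr2, Ugt2b35, Clic6, Rec8 and Keap1. The other 46 reached an adjusted p between 0.0518 and 0.226 in 1 or more of them.

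The comparison of KD IRI with WT IRI asks what lower Keap1 does in the injured kidney. NRF2 targets were higher again: Gpx2 rose 14.1-fold (log2 3.82 ± 0.26, adjusted p = 0.00258), Cbr3 8.68-fold (3.12 ± 0.16), the glutathione transferase Gsta4 5.32-fold (2.41 ± 0.095), Nqo1 4.14-fold (2.05 ± 0.11) and Txnrd1 2.71-fold (1.44 ± 0.084). Gclc (0.93), Hmox1 (0.93) and Gclm (0.68) rose as well. Of 20 glutathione genes 13 rose, none fell and 7 did not pass (17 adjusted over the list alone), with a median of 0.92. Of 22 redox and detoxification genes 16 rose and 6 did not pass (20 adjusted over the list alone), with a median of 1.07. Of 9 NADPH genes 4 rose and 5 did not pass (6 adjusted over the list alone), with a median of 0.62, or 0.38 under the planned normexp correction. Pgd and G6pdx of the pentose phosphate pathway rose by 1.14 and 0.83. By camera, the adjusted p was 2.17e-14 for glutathione (adjusted p = 0.195 with an estimated correlation), 1.77e-17 for redox and detoxification (adjusted p = 0.0428 with an estimated correlation) and 0.000251 for NADPH supply (adjusted p = 0.22 with an estimated correlation).

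Between the injured genotypes, camera at the preset correlation passed upward for cell cycle and downward for fatty acid oxidation and proximal tubule, although most genes of these lists did not pass singly. Of 20 cell-cycle genes 8 rose, none fell and 12 did not pass (18 rose adjusted over the list alone), with a median of 1.16. Top2a, a topoisomerase, rose by 1.41 and the cyclin Ccna2 by 1.30, and Mki67 did not pass (1.38, adjusted p = 0.0625). Of 24 fatty acid oxidation genes 10 fell and 14 did not pass (23 fell adjusted over the list alone), with a median of -0.48. Ehhadh, of the peroxisome, fell by 2.07. Of 27 proximal tubule genes 10 fell and 17 did not pass (12 fell adjusted over the list alone), with a median of -0.41. The lactate transporter Slc5a12 fell by 1.65 and Slc13a1 by 1.56, while Slc34a1 did not pass (-0.39, adjusted p = 0.373). Of 9 genes of gluconeogenesis and fructose use 3 fell, among them the glucose-6-phosphatase gene G6pc (-1.91), and 6 did not pass. With camera the adjusted p came to 1.37e-10 for cell cycle (adjusted p = 0.416 with an estimated correlation; fry 0.0523) and 1.37e-10 for fatty acid oxidation (adjusted p = 0.22 with an estimated correlation). It was 1.45e-05 for proximal tubule (adjusted p = 0.644 with an estimated correlation; fry 0.0843) and 0.000382 for gluconeogenesis (adjusted p = 0.496 with an estimated correlation; fry 0.0523). Without WT IRI 1 the proximal tubule adjusted p was 0.0927 and the median -0.094; the median was -0.72 without WT IRI 2 and -0.62 without KD IRI 1. The gluconeogenesis median was -0.75 without WT IRI 2. Under the planned normexp correction the medians were -0.30 for fatty acid oxidation and -0.28 for gluconeogenesis.

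Few injury and inflammation genes passed between the injured genotypes. Of 24 tubule injury genes 4 rose, none fell and 20 did not pass (6 rose and 2 fell adjusted over the list alone), with a median of 0.35. The transcription factors Fosl1 (1.97) and Myc (1.20) rose, while Havcr1 (0.69, adjusted p = 0.279) and Lcn2 (-0.37, adjusted p = 0.691) did not pass. Of 21 inflammation genes 1 rose, Il1rn, which blocks the interleukin 1 receptor (1.963), and 20 did not pass (1 rose adjusted over the list alone). The median of 0.51 was -0.046 under the planned normexp correction, 0.29 under the added one and 0.34 without KD IRI 2. Without WT IRI 1 the tubule injury median was 0.11 (camera adjusted p = 0.227), and without WT IRI 2 it was 0.73. In camera's test the adjusted p was 0.001 for tubule injury (adjusted p = 0.693 with an estimated correlation; fry 0.238) and 0.00199 for inflammation (adjusted p = 0.229 with an estimated correlation; fry 0.0523). No neutrophil (median -0.23, camera adjusted p = 0.954, the test pointing up), macrophage (0.30, camera adjusted p = 0.059) or lymphocyte marker (0.25, camera adjusted p = 0.625, or a median of -0.89 under the planned normexp correction) passed. Loop and distal tubule genes had 2 falls, Egf (-1.03) and Wnk4 (-0.68), and 10 not passing (camera adjusted p = 0.00294; adjusted p = 0.22 with an estimated correlation). Collecting duct genes had 3 falls, such as the sodium channel subunits Scnn1g (-0.73) and Scnn1a (-0.69), and 10 not passing (camera adjusted p = 0.00335; adjusted p = 0.313 with an estimated correlation). Matrix and stroma genes had 3 rises and 14 not passing (median 0.18; camera adjusted p = 0.0179; adjusted p = 0.821 with an estimated correlation; fry 0.403). Their median was -0.0095 without WT IRI 1 and -0.037 without KD IRI 2 (camera adjusted p = 0.522 and 0.411), and 0.38 without WT IRI 2 and 0.34 without KD IRI 1. No gene of the TCA cycle list passed singly (median -0.14; camera adjusted p = 0.0464; adjusted p = 0.821 with an estimated correlation; fry 0.208), and this list passed camera neither without WT IRI 1 (0.49) nor without KD IRI 2 (0.338) nor without any 1 uninjured array (0.0619 to 0.0629). Its median was 0.0071 under the planned normexp correction. Without WT IRI 2 the loop and distal tubule median was -0.57, as it was without KD IRI 1, and without WT IRI 1 that of collecting duct was -0.51. Outside the lists, Ugt2b35 was at least 17.9-fold higher, Slc16a14 at least 6.78-fold lower and Astn1 at least 5.18-fold lower.

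Between the injured genotypes 1481 genes changed, 772 higher and 709 lower, 444 of them by at least 2-fold. Between slides the change correlated with r = 0.568 across genes, and the count was 1814 with a slide block. Medians within slides were 1.09 and 0.74 for glutathione, 1.03 on both for redox and detoxification, 0.72 and 0.51 for NADPH supply, 0.57 and 1.78 for cell cycle, -0.41 and -0.57 for fatty acid oxidation, -0.58 and -0.35 for proximal tubule, 0.67 and 0.17 for tubule injury and 0.38 and 0.75 for inflammation. The count was 24 without KD IRI 2, 220 without KD IRI 1, 295 without WT normal 1 and 295 without WT normal 2, 958 without the intensity trend and 67 with only the arrays compared. Of 51 named genes past the threshold, 9 kept their call in each of the 8 fits that left out 1 array: Ugt2b35, Gpx2, Cbr3, Gsta4, Nqo1, Txnrd1, Keap1, Slc16a14 and Astn1. The other 42 reached an adjusted p between 0.0563 and 0.255 in 1 or more of them.

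**Figure D2:**
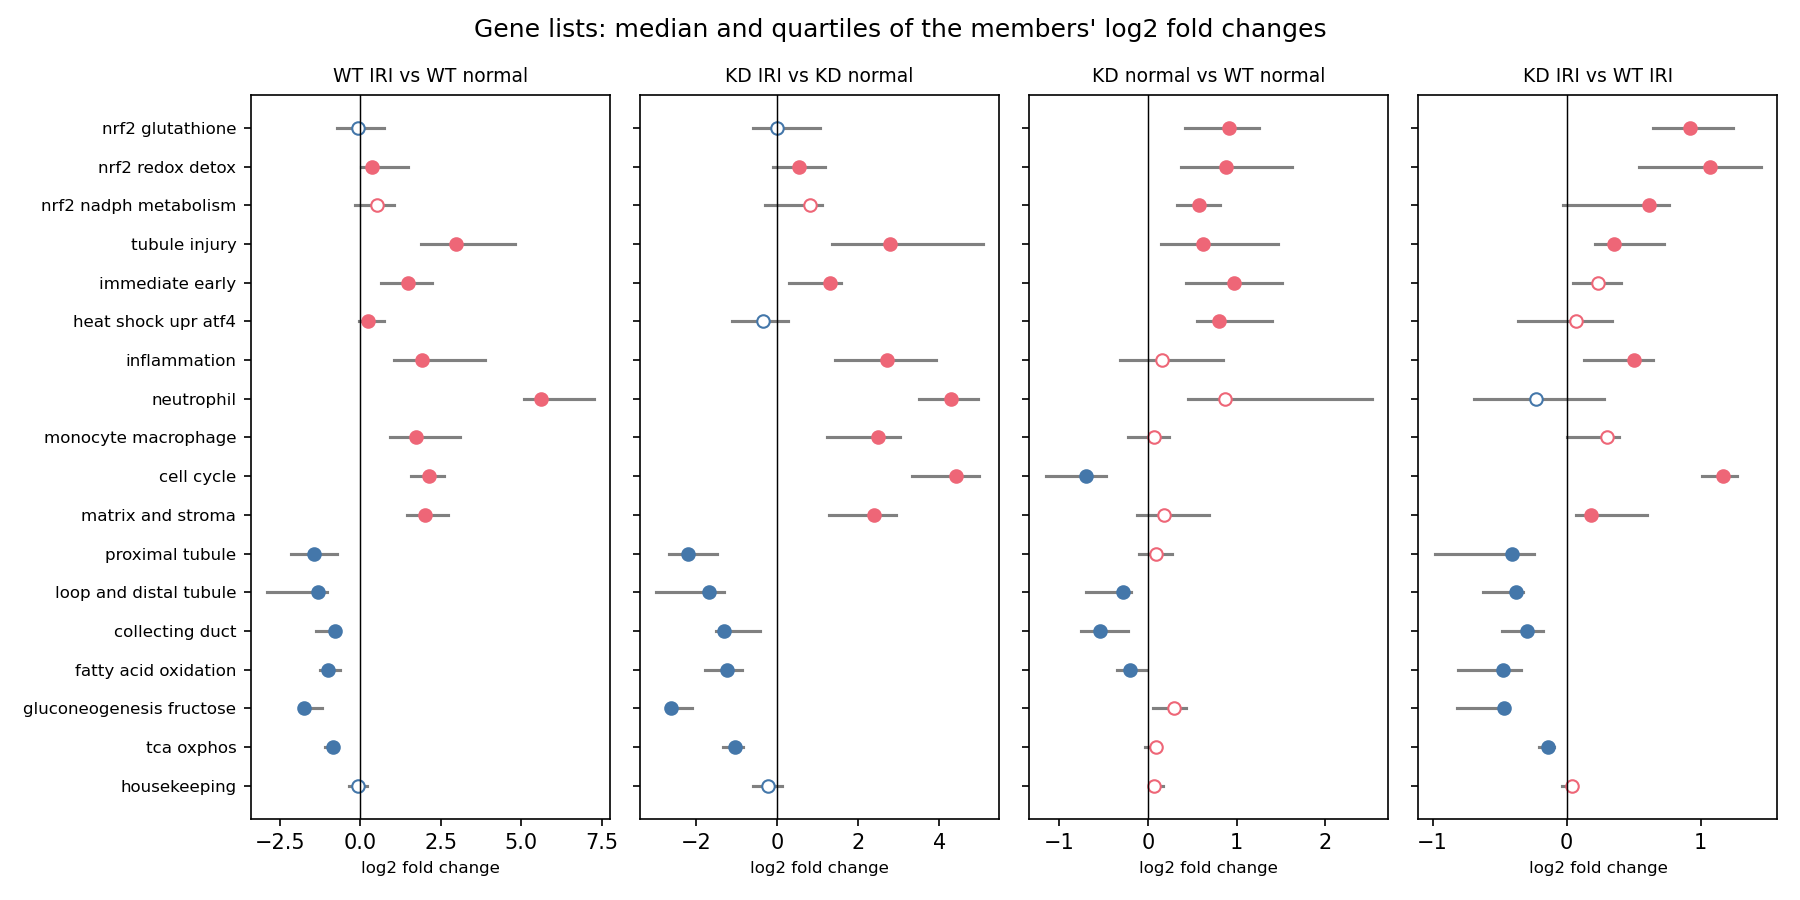
Median log2 change (point) and quartiles (line) of the measured genes of 18 lists in 4 comparisons; filled points passed camera's adjusted p at the preset correlation, red above 0 and blue below 0. In the cell-cycle list the median is 2.15 after injury in WT and 4.40 in KD.

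The comparison of KD IRI with KD normal asks how the KD kidney responds to injury. Havcr1 rose 409-fold (log2 8.67 ± 0.37, adjusted p = 1.57e-05), Krt20 127-fold and Lcn2 76-fold, and genes of DNA replication and mitosis rose. Uhrf1, which maintains DNA methylation during replication, rose 123-fold, the mitotic kinase Cdk1 46.5-fold and Aurkb at least 25.3-fold. Of 20 cell-cycle genes 19 rose and 1, Bub1 (with another probe called the opposite way), fell, with a median of 4.40. Of 24 tubule injury genes 20 rose, 1 fell, Igfbp1 (-4.60), and 3 did not pass (21 rose and 1 fell adjusted over the list alone; median 2.78). Of 21 inflammation genes 19 rose and 2 did not pass (median 2.71, or 2.12 with bounds), such as Il1rn, at least 69.7-fold higher. The inflammation median was 0.74 under the planned normexp correction and 1.35 under the added one. All 27 proximal tubule genes fell (median -2.21), among them Slc22a7 (-7.24) and Slc34a1 (-2.45), and of 24 fatty acid oxidation genes 21 fell and 3 did not pass (median -1.24), among them Ehhadh (-3.55) and Acadm (-2.73). Camera's adjusted p was 5.23e-09 for cell cycle, 1.03e-08 for tubule injury, 6.77e-09 for proximal tubule and 1.05e-07 for fatty acid oxidation (adjusted p = 0.352 with an estimated correlation for these 4 lists), and 7.12e-07 for inflammation (adjusted p = 0.178 with an estimated correlation).

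Markers of neutrophils rose in 9 of 11 (median 4.28, or 3.83 with bounds; camera adjusted p = 0.00181; adjusted p = 0.475 with an estimated correlation), such as Csf3r, at least 30.2-fold. Those of macrophages rose in 15 of 17 and fell in 1 (median 2.50; camera adjusted p = 9.33e-06; adjusted p = 0.352 with an estimated correlation), such as Msr1, at least 22.4-fold. Under the planned normexp correction the medians were 1.49 for neutrophils (2.32 under the added one) and 1.55 for macrophages. Collagen genes were among the matrix genes that rose, Col1a1 39.6-fold and Col3a1 16.8-fold; 14 of 17 matrix and stroma genes rose and 3 did not pass (camera adjusted p = 2.11e-06; adjusted p = 0.369 with an estimated correlation). All 9 genes of gluconeogenesis and fructose use fell (median -2.62; camera adjusted p = 3.27e-05), such as G6pc (-4.87). So did all 21 of the TCA cycle list (median -1.06, or -0.66 under quantile normalization; camera adjusted p = 2.86e-08) and all 12 of the loop and distal tubule (median -1.69; camera adjusted p = 1.69e-05). With an estimated correlation these had an adjusted p = 0.352, 0.352 and 0.178. Among NRF2 targets in KD kidney Gpx2 (2.38), Akr1b8 (2.43), Txnrd1 (0.83) and Nqo1 (0.73) rose, whereas Hmox1 (-0.74) and Gclc (-0.57) fell. Of 22 redox and detoxification genes 13 rose and 4 fell (camera adjusted p = 0.00854, adjusted p = 0.352 with an estimated correlation). Of 20 glutathione genes 8 rose and 8 fell (camera adjusted p = 0.8485), and of 9 NADPH genes 6 rose and 3 fell (camera adjusted p = 0.169).

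In KD kidney 12170 genes changed with injury, 5819 higher and 6351 lower, 5457 of them by at least 2-fold. Here too quantile normalization turned the balance, with 6470 higher and 5618 lower, while both normexp fits and the deposited log2 table did not. Across genes the change correlated between slides with r = 0.915, and the count was 12840 with a slide block. Medians within slides were 2.91 and 2.66 for tubule injury, 2.83 and 2.33 for inflammation, -2.01 and -2.43 for proximal tubule, -1.35 and -1.24 for fatty acid oxidation and 4.07 and 4.67 for cell cycle. The count was 6943 with the planned normexp correction, and no left-out array moved it by more than 1.5 times (9242 to 12529). Of 95 named genes past the threshold 84 kept their call in each of the 8 fits that left out 1 array. The other 11, including Bub1, reached an adjusted p between 0.051 and 0.152 in 1 or more of them.

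The interaction tests whether the injury response differed with genotype. Cell-cycle genes rose more with injury in KD than in WT: 14 of 20 had a positive interaction past the threshold, none a negative one and 6 did not pass (19 adjusted over the list alone; median 1.90). Of the 17 that were above background on at least 1 array of every group, 11 passed, with a median of 1.87. Under the planned normexp correction the median of the list was 1.20. Of 27 proximal tubule genes 6 passed with a negative interaction and 21 did not pass (8 passed adjusted over the list alone; median -0.53), such as Slc13a1 (-1.20 in KD, 0.88 in WT) and Cyp2e1 (-4.43 in KD, -2.46 in WT). In gluconeogenesis and fructose use 2 of 9 genes passed with a negative interaction (8 adjusted over the list alone; median -0.76), such as G6pc (-4.87 in KD, -1.85 in WT). In fatty acid oxidation 2 of 24 did (7 adjusted over the list alone; median -0.32), among them Ehhadh. Few stress-response genes passed. In the immediate-early list it was 1 of 11 (8 adjusted over the list alone; median -0.72), Egr2 (1.86 in KD, 4.29 in WT), with a negative interaction. In the heat-shock list it was 3 of 18 (4 adjusted over the list alone; median -0.78), such as Hspb1 (1.76 in KD, 3.64 in WT), also with a negative interaction. In KD against WT the medians of these lists were 0.97 and 0.80 without injury, but 0.23 and 0.07 with injury. By these medians the negative interactions went with higher levels in uninjured KD kidney, not with lower levels in injured KD kidney. Camera gave an adjusted p of 2.64e-11 for cell cycle, 0.000107 for proximal tubule and for heat shock, 0.000125 for gluconeogenesis, 0.000866 for fatty acid oxidation and 0.000625 for immediate-early genes. Each had an adjusted p = 0.906 with an estimated correlation, and with fry none passed (0.146 to 0.23). The 3 NRF2 lists did not pass (camera adjusted p = 0.561, 0.861 and 0.996). In redox and detoxification and in NADPH supply the medians were 0.08 and 0.10 and the means -0.048 and -0.087. Under the planned normexp correction these 2 medians were 0.39 and 0.37. Hmox1 had an interaction of -3.27 ± 0.22 (adjusted p = 0.00573), Gclc one of -1.08 and Gpx2 one of 1.90. Both Hmox1 and Gclc were higher in KD than in WT with and without injury, by less with injury. Tubule injury (median -0.28, or -0.0087 under the planned normexp correction, camera adjusted p = 0.217) and inflammation genes (median 0.23, camera adjusted p = 0.561) did not pass.

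The interaction passed for 1342 genes, 780 positive and 562 negative (1593 with a slide block), 787 of them by at least 2-fold. This count was 5 without WT normal 1, 9 without WT normal 2, 14 without KD IRI 2, 217 without KD IRI 1 and 432 without KD normal 2. It was 636 from the deposited log2 table, 758 without the intensity trend and 572 without the filter on dim probes. Of 53 named genes past the threshold only Slc16a14, with a fitted interaction of -4.07, kept its call in each of the 8 fits that left out 1 array. The other 52 reached an adjusted p between 0.0506 and 0.178 in 1 or more of them. The proximal tubule median was -0.22 without WT IRI 1 and -0.85 without WT IRI 2. Under the planned normexp correction it was -0.29, that of gluconeogenesis -0.45, that of fatty acid oxidation 0.0052 and that of inflammation -0.63, with a median over all genes of -0.30.

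**Figure D3:**
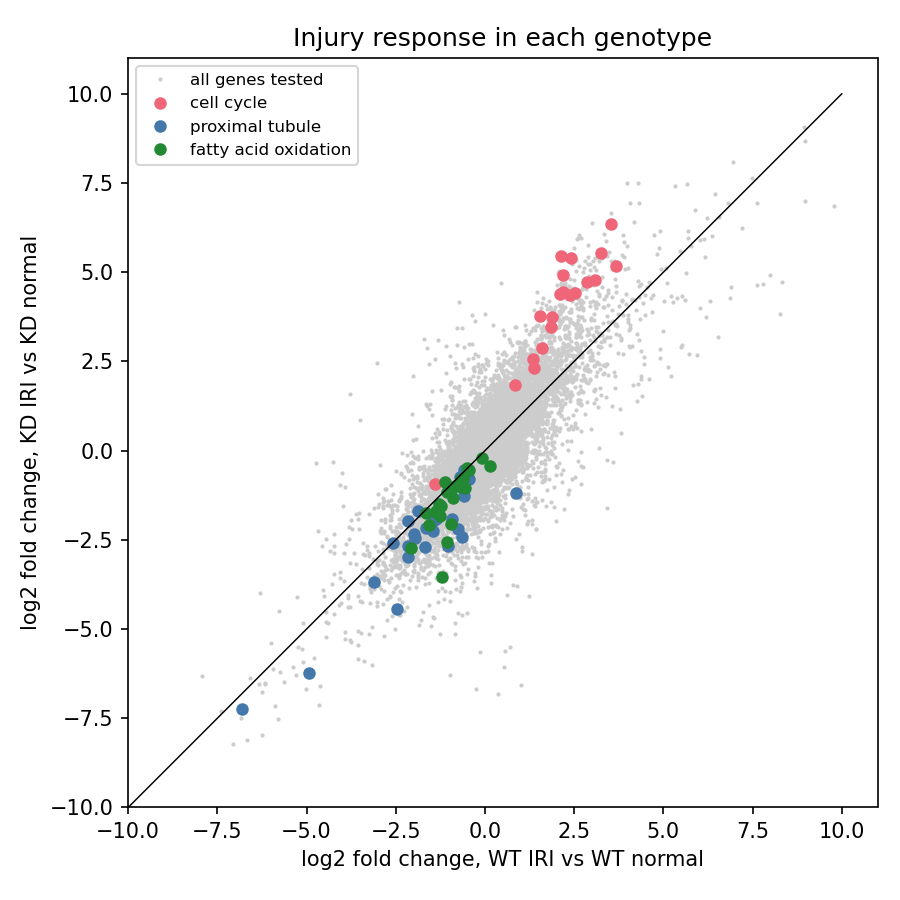
Log2 change with injury in KD (vertical axis) against WT (horizontal axis) of all genes tested, with the cell-cycle, proximal tubule and fatty acid oxidation lists in colour; the diagonal marks equal change. The median of the cell-cycle genes is 4.40 in KD and 2.15 in WT.

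Across the 20580 genes, which are not independent replicates, the genotype effect without injury correlated weakly with that under injury (Pearson's r = 0.064, Spearman's rho = 0.118). The sign of r changed to -0.38 with the planned normexp correction and to -0.039 without WT IRI 1; it was 0.159 without WT IRI 2 and 0.031 without KD normal 1. Of 467 genes called in both genotype comparisons 202 were higher in both, where independence gives 48.95, 165 were lower in both, where it gives 63.5, and 100 changed in opposite directions, where it gives 114.1. The injury responses of the genotypes correlated with r = 0.82 and rho = 0.793; of 7927 genes called in both, 3699 were higher in both, 4138 lower in both and 90 opposite. The genotype comparisons share no array with each other, and neither do the injury comparisons. All comparisons share 1 variance estimate per gene, however, so their calls are not independent and the values under independence are not chance levels.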

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

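Of the tests below, those of scaling between arrays, of leukocytes and of feeding in 16 genes were chosen only after the result was seen. The clock and fasting groups were chosen after the main results but before their own values were seen, and the readings of time of day and linked DNA were made stricter after their values were known. Apart from the 3 patterns at the end, each result here is a difference between WT and KD in the response to injury, found by limma's interaction term with n = 2 arrays per group. The interaction passed for 1342 genes. Fitted interactions of genes below background in 1 or more groups, such as Top2a, Ccnb1, Atp13a4, Doc2b, Cyp2b10, Alkal2 and Grem1, are not bounds.

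Positive interactions (log2), where KD rose more or fell less than WT, were 4.15 for Atp13a4, 3.99 for Doc2b, 3.91 for Clic6, 3.52 for Dtl, 3.48 for Sppl2c, and 3.40 for Iqgap3. Further ones were 3.36 for Rad54l, 3.34 for Igf2bp3, 3.33 for Ccnb1, 3.28 for Lrrn2, 2.995 for Top2a, and 2.32 for Aif1. Smaller ones were 1.90 for Gpx2, 1.79 for Il1rn, 1.70 for Col1a1, 1.18 for Ptgr1, and 1.13 for Gsta4. Those under 1 were 0.95 for Vcam1, 0.93 for Abcc1, 0.83 for Pdk1, 0.71 for Nqo1, 0.65 for Tcf21, 0.62 for Col1a2 and 0.49 for Taldo1.

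Negative ones were -0.50 for Scnn1g, -0.98 for Idh1, -1.08 for Gclc, -1.10 for Acta2, and -1.14 for Gdf15. They were -1.26 for Tnfrsf12a, -1.32 for Ndrg1, -1.50 for Herpud1, -1.58 for Slc37a4, -1.88 for Hspb1, -1.96 for Krt19, and -1.97 for Cyp2e1. More negative interactions were -2.08 for Slc13a1, -2.22 for Nlrp3, -2.33 for Ehhadh, -2.44 for Egr2, -3.03 for G6pc, -3.27 for Hmox1, and -3.93 for Zdbf2. At the end of the range were -3.98 for Sh2d1a, -4.07 for Slc16a14, -4.24 for A2m, -4.55 for Astn1, -5.05 for Fga, -6.18 for Alkal2, -6.21 for Grem1, -6.60 for Angptl7 and -7.19 for Cyp2b10.

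Among the gene lists the camera adjusted p of the interaction was 2.64e-11 for cell cycle, 0.000107 for proximal tubule, 0.000107 for heat shock, 0.000125 for gluconeogenesis and fructose use, 0.000625 for immediate-early genes, 0.000866 for fatty acid oxidation, 0.00869 for the TCA cycle and 0.0177 for lymphocytes. All 8 had an adjusted p = 0.906 with an estimated correlation, and the lymphocyte median of 1.11 was -1.10 under the planned normexp correction, while that of the TCA cycle turned from -0.196 to 0.131 and that of fatty acid oxidation from -0.32 to 0.0052. Lymphocytes had a camera adjusted p of 0.0957 without KD normal 2, and the TCA cycle one of 0.0949 without WT IRI 1 and 0.0529 without KD IRI 2.

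The first pattern is the cell-cycle list, higher in KD IRI than in WT IRI with a median of 1.16 (camera adjusted p = 1.37e-10, but 0.416 with an estimated correlation and 0.0523 with fry); 8 of its 20 genes passed singly. Quantile normalization gave 1.19 (95% bootstrap interval over genes, which ignores their correlation, 1.07 to 1.27) and the planned normexp correction 1.03, which argues against scaling as its source. Leaving out 1 injured array gave at least 0.796 (without WT IRI 2), which argues against a single array as the whole source of the list's median. Its size still varied, with 0.57 on slide 1 and 1.78 on slide 2, and the calls of Top2a and Ccna2 were each kept in 1 of the 8 fits without 1 array. Leukocyte markers had a median of 0.18 over 39 genes with an upper bound of 0.308, below the cell-cycle median. By list the medians were -0.23 for neutrophils, 0.30 for macrophages and 0.25 for lymphocytes. Markers of all leukocytes need not rise as much as genes of dividing ones, so this cannot decide whether leukocytes contribute. The position on the slide cannot be told apart from the group, and an effect of the knockdown itself stays open as a hypothesis.

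The second pattern is the immediate-early and heat-shock lists, higher in KD normal than in WT normal by camera at the preset correlation. With an estimated correlation their adjusted p was 0.373 and 0.233. Under quantile normalization their medians were 0.90 (0.318 to 1.68) and 0.745 (0.553 to 1.24), against 0.97 and 0.80. Under quantile normalization and the planned normexp correction the genes moved, in the median, by at most -0.161 (-0.23 to -0.025) and -0.128 (-0.148 to -0.082). The added normexp fit gave medians of 0.67 and 0.81. The movements are small beside the medians, which argues against scaling as the whole source of either. For the immediate-early list this reading rests on the movements alone. They were examined after the interval of its median had left scaling open. Genes of the Arntl phase of the circadian clock lay 1.88 above those of the Per phase (interval 0.268 to 2.97), but the Per group itself had a median of -0.023 (-0.67 to 0.45), so a different time of day at harvest may or may not contribute. Fasting-responsive genes had a median of -0.51 over 12 genes (-0.78 to 0.11) and of -0.47 over 16 (-0.70 to -0.076), the latter with genes first left out because their values had been seen. Both exclude a change of 1 or more, and so a large difference in feeding as measured by these genes, but not a smaller one. Handling at harvest was not recorded in the labels, and an effect of the knockdown stays open as untested.

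The third pattern is genes changed the same way by the knockdown with and without injury outside the NRF2 lists. DNA around Keap1 carried along with the modified allele could bring such changes: 2 of 177 genes near Keap1 (1.13%), Angptl6 and Ppan, were called the same way in both comparisons, against 261 of 13877 others (1.88%), a ratio of 0.601. Its upper bound of 2.40 does not exclude a 2-fold excess (Fisher's exact p = 0.776). An effect of lower Keap1 itself stays open and was not tested separately.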

How the results depend on the processing

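The normexp fit without non-uniform spots was chosen after seeing the data; the other alternatives were planned. Of 104 alternative counts 73 stayed within 1.5 times, and for named genes 7565 of 8793 values kept direction and side of the threshold (995 lost the call, 212 gained it, 21 turned). Keap1 kept direction and call in 37 of 38; with only the arrays compared it was -1.39 (adjusted p = 0.0503). Of 325 set tests of the primary lists 296 kept their side and of 1300 of the other lists 1171 did.

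In the order WT IRI against WT normal, KD normal against WT normal, KD IRI against WT IRI, KD IRI against KD normal and interaction, counts with a 2-fold minimum were 3448, 897, 444, 5457 and 787. Leaving out 1 array gave 5891 to 9653, 122 to 3866, 24 to 1579, 9242 to 12529 and 5 to 1687; the lone array left is assumed to vary like the other groups. The planned normexp gave 5202, 1326, 1339, 6943 and 1031. Of these, 4966, 973, 760, 6713 and 550 were also called in the main fit. Its all-gene median was 0.218, 0.145, -0.212, -0.314 and -0.298. Its estimated background mean was -220.5 on KD normal 1 and -442.6 on WT IRI 2, against 2.66 to 7.67 elsewhere. Without non-uniform spots (63 and 30 on these arrays) it was 4.998 and 6.84, and the counts were 9931, 2408, 1436, 12395 and 921. No filter gave 15081, 1981 and, for the interaction, 572, while no intensity trend gave 958 in KD IRI against WT IRI and 758 for the interaction. The deposited log2 table gave 636 for the interaction, and only the arrays compared gave 67 in KD IRI against WT IRI. Apart from the fewer samples, genes or folds of an alternative's own construction, the cause was not tested.

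A slide block, the same fit as the replicate block, gave 10106, 3727, 1814, 12840 and 1593. Arrays with the same number share a slide, and their deviations correlated positively in all 6 pairs of groups (0.0216 to 0.262, 4 of them at 0.113 or more). A shared effect of the slide is therefore open, but with 2 pairs at 0.0216 and 0.059 the numbers were not treated as pairing samples. The scan-date block was not run.

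Set tests with an estimated correlation (adjusted p) gave, for tubule injury, inflammation, proximal tubule and fatty acid oxidation, 0.27, 0.116, 0.312 and 0.27 in WT IRI against WT normal. They were 0.693, 0.229, 0.644 and 0.22 in KD IRI against WT IRI, and 0.352, 0.178, 0.352 and 0.352 in KD IRI against KD normal. For glutathione, redox and NADPH they were 0.233, 0.0776 and 0.233 without injury, and 0.195 and 0.22 (glutathione, NADPH) with injury. In the interaction proximal tubule and fatty acid oxidation had 0.906 each, and 0.23 and 0.166 with fry. In KD IRI against WT IRI fry gave 0.238 for tubule injury, 0.0523 for inflammation and 0.0843 for proximal tubule. The tubule injury interaction was 0.0218 without the filter, and without 1 array it ranged from 0.0141 to 0.759. Without 1 array tubule injury in KD IRI against WT IRI ranged from 2.26e-06 to 0.227 and proximal tubule from 2.17e-10 to 0.0927.

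Of the reversals, Bub1 went to 1.11 (WT IRI against WT normal) and 2.24 (KD IRI against KD normal) with the mean of its probes. With the planned normexp, none passing, KD normal against WT normal gave 0.75 for Aurkb, 0.52 for Ccnb1, 0.35 for Prtg and 0.16 for Olfr774. KD IRI against WT IRI gave -0.015 for Olfr19, -0.040 for Atp13a4, -0.51 for Igf2bp3, -0.64 for Slco1b2, -0.68 for Doc2b and -0.50 for Sppl2c. KD IRI against KD normal gave -0.32 for Ms4a1 and -0.81 for Gzma. Its interactions were -1.09 for Atp13a4, -1.56 for Doc2b, -0.32 for Clic6, -1.40 for Sppl2c, -1.34 for Igf2bp3, -0.21 for Ccnb1 and -1.16 for Lrrn2. The correlation of genotype effects was -0.381 with the planned normexp, 0.120 with the added one, 0.0195 without the filter, 0.124 with probes above background on all arrays, and -0.0392 to 0.159 without 1 array. Signal over background limits dim genes: 707, 270, 85 and 1063 of the genes called in the first 4 comparisons were below background in 1 group.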

Other observations

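The gene families were chosen after the main results were seen, and so were the clock and fasting groups, before their own values were. Families were tested for enrichment by the stem of their symbols over 228 stems with Fisher's exact test. This test treats genes as independent, so its p-values ignore their correlation and do not measure the spread between arrays. Some families share called members with the fixed lists and in part repeat those results. Abcc3 and Abcc4 are in the redox list, Dnajb9 in the heat-shock list, and Mcm2, Mcm3 and Mcm6 in the cell-cycle list. Several Slc genes, such as Slc5a12 and Slc7a9, are in the proximal tubule list. In KD IRI against WT IRI, genes of the nuclear pore were higher: 12 of 20 Nup genes rose (adjusted p = 1.70e-09), such as Nup62 (0.99) and Nup43 (0.76). The Mcm genes of the replication helicase rose in 7 of 10 (adjusted p = 5.18e-06), such as Mcm10 (1.32) and Mcm3 (1.23), and Rrp genes of ribosomal RNA processing in 4 of 8 (adjusted p = 0.0205). Cytochrome P450 (Cyp) genes fell in 14 of 57 (adjusted p = 3.22e-06), such as Cyp2d34 (-2.02) and Cyp4f15 (-1.67), and solute carriers (Slc) in 29 of 300 (adjusted p = 0.000284), such as Slc1a2 (-1.79) and Slc7a9 (-1.16). The medians of these families kept their sign under the scaling alternatives run.

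In KD normal against WT normal, Dnajb co-chaperone genes rose in 6 of 9 (adjusted p = 0.00236), such as Dnajb9 (0.83). Abcc transporters rose in 5 of 8 (adjusted p = 0.0109), such as Abcc4 (1.72) and Abcc3 (1.03), and Utp genes of ribosome assembly in 5 of 10 (adjusted p = 0.0288). Kallikrein (Klk) genes fell in 9 of 17 (adjusted p = 0.00232), such as Klk1b26 (-1.23); their sequences are near-identical, so probes may not tell them apart, and the family median was -0.0175 under the planned normexp correction. In both genotype comparisons 3 of 10 Utp genes rose (adjusted p = 0.0444), while 4 of 37 Lrrc and 3 of 17 Klk genes fell (adjusted p = 0.0459 each); the Lrrc median without injury turned to 0.049 under the planned normexp correction. Clock genes of the Arntl phase rose in KD normal, Nfil3 by 2.50 (adjusted p = 0.00415), Arntl by 1.86 (adjusted p = 0.00889) and Clock by 0.48 (adjusted p = 0.0152). Of 10 Per-phase genes only 1 passed, Nr1d1, with a fall of 0.95 (adjusted p = 0.0312), and the Per-phase median was -0.023. The difference of 1.88 between the phase groups thus came from the 3 Arntl-phase genes. Their rise was not particular to KD normal. In WT IRI against WT normal, which shares the WT normal arrays, all 3 Arntl-phase genes rose (median 1.15). There, unlike in KD normal, 8 of 10 Per-phase genes fell (median -1.51). In KD IRI against KD normal 7 of 10 Per-phase genes and 2 of 3 Arntl-phase genes fell, and in KD IRI against WT IRI no gene of either group passed with limma. The interaction was -2.90 for Nfil3 (adjusted p = 0.0166) and -1.96 for Arntl (adjusted p = 0.0332). In KD IRI against WT IRI the fasting-responsive group had a median of -1.11, with 5 of 12 genes lower.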
